A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

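DNase I hypersensitivity was measured by sequencing in 2 yeast libraries, 1 from a WT strain and 1 from a strain with the Hsp90 allele G170D, both in the BY4741 background. Per the labels, cultures in YPD started at an OD of 0.25 (WT) or 0.37 (G170D) and were kept at 37 °C for 6 h, until the OD reached 0.65 to 0.7. Nuclei were treated briefly with DNase I, fragments were selected by size, and libraries were sequenced for 101 cycles on 2 lanes. The labels describe the selected fragments as short and also give a size above 650 bp, and which of these applied is unknown. Reads were aligned with Bowtie 0.12.8 to sacCer3 and checked with FastQC as far as the submitters' processing notes name these tools. The caller of the DHS and its threshold are not given in the sources used here. The names of the footprint lists refer to dnase2tf. Per library the authors deposited a list of DHS and a list of footprints, each region with a score whose formula is not given in the sources used here. The deposited DHS scores were positive and ran from 3.54 to 9903 in WT and from 3.48 to 10189 in G170D. The deposited footprint scores were negative, the most negative being strongest, and ended at -4.06 in WT and -4.10 in G170D. The footprint lists held 2 (WT) and 3 (G170D) infinite scores, which were ranked as strongest. Lists called separately in each library vary in length with sequencing depth and threshold, and DHS of a list lay at least 151 bp apart, so the total depth and its share in the differences are unknown.

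Regions were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Regions overlapped when they shared at least 1 bp, and 1000 circular shifts along the chromosomes gave the overlap of unrelated lists. Footprints were counted by midpoint, and 100 random offsets along the length covered by both strains gave the overlap of unrelated footprints. Genes came from an R64 gene table, the same assembly as sacCer3, and coordinates are counted from 1. The strand was read from the systematic name. Coding lengths were multiples of 3 for 96.4% of genes, so that gene starts and ends are coding starts and ends and untranslated regions are not included. A promoter was the 500 bp upstream of the coding start of each of 6002 nuclear protein-coding genes, and a promoter DHS needed at least 1 bp in that window. Shares have exact Clopper-Pearson intervals, and ratios of counts have intervals from the exact binomial distribution. Both strains had 1 library, so no test across replicates was made. For each of 23 gene lists the mean difference in promoter DHS length was placed among 10000 random lists of the same size. These were matched in broad classes of the mean coverage of both strains, as a description of these libraries. The lowest class joined genes with no promoter DHS in either strain and genes with little, so matching was coarse there. 1 name of the cell wall list had no match in the gene table.

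The gene lists, the comparisons, the alternatives and the rule for named genes were chosen before the data were examined, except where a later choice is stated. The rule took the Hsp90 genes HSC82 and HSP82, the 10 largest WT-only and 10 largest G170D-only promoters of genes with a standard name (ties broken by footprint number, then by DHS width; genes sharing a DHS counted once), up to 3 members of each list with the largest difference in DHS length, and the 5 widest DHS found in one strain. LEU2, TRP1 and the other auxotrophic marker genes, tRNA and snoRNA genes named individually, and strong regions found in one strain were chosen after their values were seen. Alternatives were other overlap rules, windows of 300 and 1000 bp, at least 50 bp of DHS in the window, lists of the same number, width limits, and score thresholds. The comparison of promoters and lists was tested on simulated data made from the WT list for all 6002 genes. In it, 100 of 100 removed regions and 100 of 100 added promoter regions were found. Of 200 random lists without an effect, 4 lay outside the central 95%. All 20 lists in which 10 of 20 genes were already called WT only were found, which was set by construction. The simulated lists differed at the changed regions alone, so the simulation checked the calculation and not error or power in the real lists. A planned count of 30 sequence motifs in footprints was not run, since no genome sequence was used here. Centromeres, replication origins and long terminal repeats were not analysed here.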

Results

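DNase I hypersensitive sites (DHS), stretches of chromatin cut readily by DNase I, were mapped in the budding yeast Saccharomyces cerevisiae in a wild-type (WT) strain and in a strain carrying the temperature-sensitive Hsp90 allele G170D. Hsp90 is an abundant chaperone encoded in yeast by HSC82 and HSP82. Both strains had the laboratory background BY4741 and were grown in rich medium at 37 °C for 6 h before nuclei were taken. Cultures started at an OD of 0.25 in WT and 0.37 in G170D and both ended at 0.65 to 0.7. Growth over the 6 h thus differed and cannot be separated from strain. The comparison asked how open chromatin and the short protected stretches within it, called footprints, differed between the strains. There was 1 library per strain and so no replicate error. Each value below describes these 2 libraries, the number of reads behind each list is unknown, and intervals are exact 95% intervals that cover counting error only. They treat items as independent. Neighbouring genes can share a DHS, so intervals for shares of genes can be too narrow. The WT lists held 3155 DHS and 45019 footprints, and the G170D lists held 2875 DHS and 33585 footprints. Scores of DHS and footprints are the authors' values and were used here to rank items within a list.

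The listed DHS covered 2183 kb in WT and 1807 kb in G170D, or 18.1% and 15.0% of the chromosomes, a difference of -17.2% in length and -8.87% in number. The DHS over LEU2, a leucine synthesis gene on chromosome III that BY4741 is known to lack, spanned 90675 to 93422 in WT and 90674 to 93361 in G170D (sacCer3), and ranked at place 2 by score in each list. If the strains lack LEU2, as their background implies, this signal did not come from the native gene. Whether it came from a marker or plasmid, or whether the strains differ from the labelled background, is unknown. Of the WT DHS, 892 (28.3%, 26.7 to 29.9) overlapped no G170D DHS, and 508 of the G170D DHS (17.7%, 16.3 to 19.1) overlapped no WT DHS. When a list was shifted along each chromosome at random, these shares averaged 71.8% and 69.0%. Regions found in one strain were narrow, with a median width of 194 bp in WT and 186.5 bp in G170D, against 720 and 553 bp for shared regions. Most of the length covered in WT alone, 435 kb, lay in DHS that overlapped a G170D DHS and reached further, and 203 kb lay in DHS found in WT alone. The corresponding lengths in G170D were 147 and 115 kb.

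The widest DHS found in WT alone spanned 1674 bp on chromosome IX (220716 to 222389), over the serine synthesis gene SER33 and next to RPN2, which encodes a proteasome subunit, and held 31 footprints. The others of the 5 widest lay over CUL3 and PEX31 (VII:502022-503509), DAL2 and DCG1 (IX:411583-412890), LEU5 and TCD1 (VIII:109155-110087) and STE5 (IV:659662-660561). The widest DHS found in G170D alone spanned 1180 bp on chromosome XI (277937 to 279116), over SRX1, which encodes sulfiredoxin, and upstream of the malate dehydrogenase gene MDH1, and held 33 footprints. The others lay over RSM7 (X:638912-640073), MRP20 and PDR15 (IV:1278251-1279365), DMO1 and ATP2 (X:646680-647707) and SLK19 and LIP5 (XV:714790-715799). Strong regions were found in one strain alone at different rates. In the top quartile of each list by score, 1 of the WT DHS (0.127%, 0.00321 to 0.704) and 17 of the G170D DHS (2.37%, 1.39 to 3.76) had no counterpart. In the lowest quartile the shares were 65.5% in WT and 39.9% in G170D. The share without a counterpart depended on the overlap rule: with overlap of at least 50% of each DHS it was 50.2% in WT and 45.3% in G170D. Among DHS at least as wide as the median of their list it was 5.45% and 3.62%.

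At the Hsp90 genes, the 500 bp upstream of the HSC82 coding start held 480 bp of DHS and 13 footprints in WT against 152 bp and 0 footprints in G170D. The WT DHS there was a 3096-bp region on chromosome XIII (629239 to 632334) that ended next to the coding start of HSC82 at 632355. Its G170D counterpart spanned 629306 to 632006. Within the HSC82 coding region itself the lists were close, with 481 bp of DHS and 11 footprints in WT and 480 bp and 12 footprints in G170D. Upstream of HSP82 (XVI:96496-98625) the windows held 165 bp and 3 footprints in WT and 146 bp and 2 footprints in G170D. Which of these genes carries the allele, and whether either locus was altered in the G170D strain, was not established here. The HSC82 difference therefore cannot be read as a chromatin change at an unaltered locus alone.

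**Figure D1:**
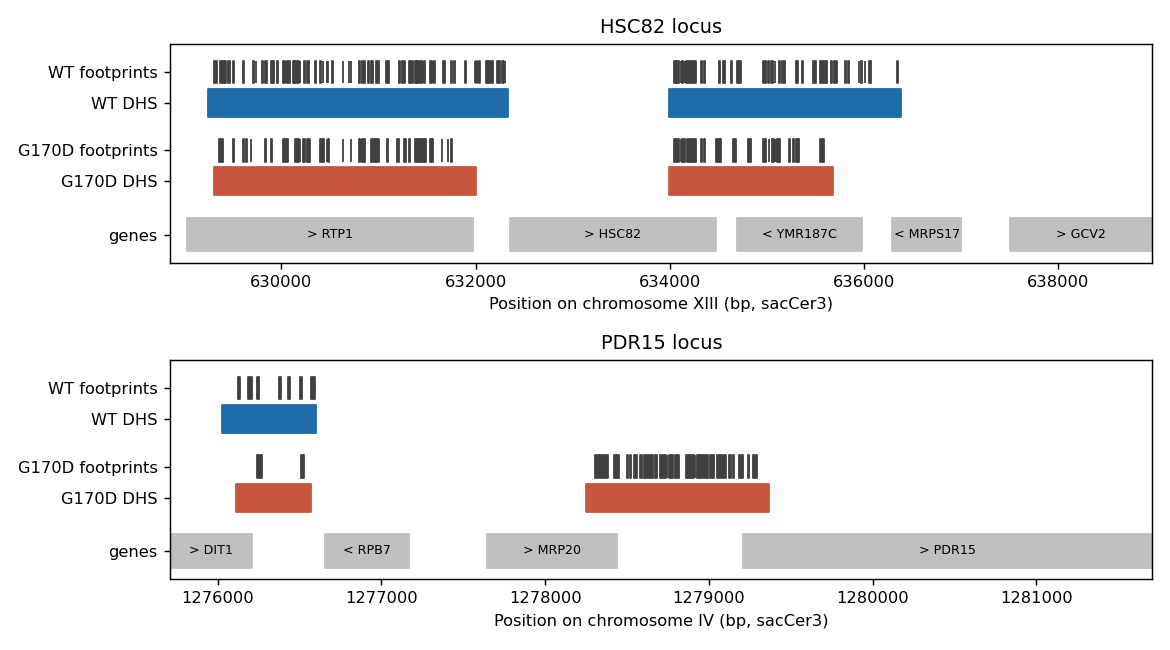
Maps of the HSC82 locus on chromosome XIII and the PDR15 locus on chromosome IV, with position in bp (sacCer3) on the x axis and genes (grey; arrowheads give the strand), DHS (blue for WT, red for G170D) and footprints (dark ticks) of each strain as separate tracks. The WT DHS upstream of HSC82 ends at 632334 and the G170D DHS at 632006, and the 1115-bp DHS at the PDR15 coding start is present in the G170D track alone.

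Promoters were compared over the 500 bp upstream of 6002 coding starts. A DHS touched the window of 1476 genes in both strains, of 423 genes in WT only, of 299 genes in G170D only and of 3804 genes in neither. With lists of the same number, 372 genes had a promoter DHS in WT only and 326 in G170D only. Promoters with a DHS made up 31.6% of genes in WT (30.5 to 32.8) and 29.6% in G170D (28.4 to 30.7). The windows were covered over 19.7% of their length in WT and 17.9% in G170D, against 18.1% and 15.0% of the chromosomes. Promoter windows were thus covered little more than the chromosomes as a whole. The share of windows that a DHS would touch by chance was not calculated. The largest WT-only promoters, each covered over the whole 500 bp in WT and not at all in G170D, were those of DUS4, a tRNA dihydrouridine synthase, with 12 footprints, VAC8, a vacuolar membrane protein, with 12, and ARF2, a small GTPase of vesicle transport, with 11. They were followed by the divergent pair PPT2 and PXA1 (10 and 7 footprints), the transport complex subunit TRS65 (10), the transcription factor subunit TAF14 (9), the ribonucleotide reductase gene RNR1 (9), the phospholipid regulator INO4 (8), DFP1 (8) and PEX31 (8). For 6 of these 10 the WT DHS overlapped a G170D DHS outside the window. Among all 423 genes, the widest WT DHS touching the window overlapped no G170D DHS for 307 (72.6%, 68.1 to 76.8).

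The largest G170D-only promoter belonged to PDR15 (IV:1279210-1283799), an ABC transporter gene of the pleiotropic drug resistance family. Its window was covered over 500 bp with 21 footprints in G170D and held none in WT. The lists carry no copy number for this or the other G170D-only regions. RSM7, a mitochondrial ribosomal protein gene, and ATP2, which encodes the beta subunit of the mitochondrial ATP synthase, had 17 footprints each, and the ATP2 region also reached the windows of DMO1 (446 bp) and of the histone demethylase gene JHD2 (311 bp). Further G170D-only windows were those of the telomerase gene EST2 (12 footprints) with TAD3 (8), the divergent pair ART5 and ROM1 (11 and 10), SPO24 (11), the splicing factor gene PRP24 (10) with TMA23 (7), IFH1, a coactivator of ribosomal protein genes, with UCC1 (10 and 9), ACH1 (10) and GDS1 (10). For 1 of these 10 regions, that of PRP24 and TMA23, the G170D DHS overlapped a WT DHS outside the window, and for 253 of all 299 genes (84.6%, 80.0 to 88.5) the region overlapped no WT DHS. Windows covered over all 500 bp in one strain and not in the other were tied, 18 in WT and 16 in G170D, and were ordered by footprint number and then by the width of the DHS. PEP1, covered over 500 bp with 8 footprints in WT, tied with INO4, DFP1 and PEX31 on footprints and had a narrower DHS.

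Gene groups were compared by mean promoter DHS length, each set against 10000 random gene lists of the same size, coarsely matched on coverage. Because 3804 of 6002 genes had no promoter DHS in either strain, genes with little coverage were matched mostly to genes with none. The difference of genes with none is 0 by construction, so percentiles of lists with low coverage can be too extreme. Promoters of the 138 genes for cytosolic ribosomal proteins were the clearest case, with 141 bp in WT and 94.2 bp in G170D, a difference of -46.7 bp that lay at percentile 0.03 of the matched lists. Of these genes 53 had a promoter DHS in both strains, 20 in WT only and 6 in G170D only. The windows of RPS14A (415 to 0 bp), RPL9B (500 to 89 bp) and RPL20B (500 to 134 bp) differed most between WT and G170D. The list stayed outside the central 95% of matched lists in each of 4 other settings, at percentiles from 0.01 to 0.16.

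The other lists outside the central range were the proteasome, galactose and ergosterol genes. Proteasome promoters (32 genes) averaged 60.8 bp in WT and 20.8 bp in G170D (percentile 1.33), with 5 WT-only and 0 G170D-only promoters, among them RPN2 (485 to 0 bp) and RPN9 (188 to 0 bp), and PUP2 held 427 and 172 bp. Ergosterol promoters (24 genes) averaged 107 and 60.8 bp (percentile 1.81), with ERG28 at 500 and 85 bp, ERG5 at 302 and 0 bp and HMG2 at 463 and 250 bp. Galactose promoters (8 genes) averaged 41.9 and 0 bp (percentile 0.06). The matched range of this list was -20 to 17.1 bp, which the coarse match at low coverage may have narrowed. The WT mean came from GAL10 (133 bp), GAL3 (120 bp) and GAL1 (82 bp), which were covered in WT only. GAL10 and GAL1 shared 1 DHS, and GAL3 lies next to TRP1, whose coding region held 646 bp of DHS in WT and 88 bp in G170D. Whether the TRP1 and GAL3 difference reflects a marker in the strains was not tested. Of 23 lists, 1.15 would lie outside the central range by chance under exact matching, which was not reached here. The proteasome list lay inside it with windows of 300 bp (percentile 2.76), the galactose list in 3 of 4 other settings (23.8 with 300 bp, 10.97 with 1000 bp, 5.17 with lists of the same number), and the ergosterol list in all 4 (2.54 to 7.46).

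The other 19 lists lay inside the central range. The 23 heat shock chaperone genes averaged 125 bp in WT and 124 bp in G170D (percentile 64.8), a difference of -1.35 bp that was 4.13 bp with windows of 300 bp and -21.8 bp with windows of 1000 bp. HSP10 held 281 bp in WT and 453 bp in G170D, SIS1 500 and 337 bp, and SSA4, an inducible Hsp70 gene, 128 and 0 bp. Hsp90 cochaperone promoters (12 genes, percentile 36.0) averaged 93.7 and 75.4 bp, with SGT1 at 339 and 231 bp, SBA1 at 500 and 422 bp and PIH1 at 23 and 0 bp. The 2 Hsp90 genes averaged 322.5 and 149 bp (percentile 17.7). General stress genes averaged 90.7 and 69.1 bp (percentile 9.81), with PNC1 at 259 and 0 bp, DDR2 at 172 and 0 bp and NCE102 at 471 and 373 bp. Genes of the unfolded protein response averaged 69.3 and 40.5 bp (percentile 12.7), with IRE1 at 247 and 0 bp, HRD1 at 500 and 415 bp and ULI1 at 75 and 3 bp.

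Chromatin genes also lay inside the central range. Promoters of the RSC remodelling complex averaged 78.6 bp in WT and 57.0 bp in G170D (percentile 21.6), with RSC1 at 500 and 117 bp, RSC58 at 306 and 352 bp and HTL1 at 31 and 0 bp. Other remodeller genes averaged 104 and 78.5 bp (percentile 9.92), with RVB2 at 434 and 0 bp, ARP5 at 500 and 199 bp and CHD1 at 336 and 457 bp. Histone genes averaged 131 and 68.1 bp (percentile 18.2; 1.26 with windows of 1000 bp), with HTB1 at 169 and 0 bp, HHT2 at 153 and 0 bp and HTA1 at 291 and 162 bp.

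Growth and metabolic groups followed. Ribosome biogenesis genes (57 genes, percentile 63.6) had 1 WT-only and 4 G170D-only promoters and averaged 152 and 145 bp, with RPA34 at 373 and 0 bp, TIF6 at 500 and 133 bp and DBP2 at 0 and 297 bp. Genes of oxidative phosphorylation and the citric acid cycle (41 genes) had 2 WT-only and 5 G170D-only promoters. Their means were 117 and 115 bp (percentile 68.0), and the difference of -2.49 bp was 2.95 bp with windows of 300 bp and 8.63 bp with windows of 1000 bp. ATP2 (0 to 500 bp) and MDH1 (0 to 494 bp) were covered in G170D, and the citrate synthase gene CIT1 held 500 bp in WT and 20 bp in G170D. Glycolysis and fermentation genes had 2 WT-only and 0 G170D-only promoters and averaged 130 and 90.1 bp (percentile 15.6), with TDH2 at 500 and 52 bp, PFK1 at 288 and 500 bp and PGK1 at 164 and 0 bp. Amino acid synthesis genes had 4 and 2 and averaged 90.6 and 81.3 bp (percentile 24.4), with LYS9 at 231 and 0 bp, TRP5 at 95 and 0 bp and LYS12 at 88 and 0 bp. Phosphate genes had 2 and 1 and averaged 84.8 and 67.7 bp (percentile 47.0), with PHO81 at 0 and 329 bp, PHM8 at 226 and 0 bp and PHO89 at 191 and 0 bp.

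Cell cycle, mating and cell surface groups completed the comparison. Genes of the G1/S transition and DNA replication averaged 69.4 and 43.4 bp (percentile 12.3), with RNR1 at 500 and 0 bp, MCM5 at 500 and 239 bp and POL30 at 0 and 81 bp. Mating pheromone genes averaged 213 and 171 bp (percentile 8.83), with PRM6 at 330 and 0 bp, STE2 at 500 and 229 bp and STE6 at 260 and 0 bp. Cell wall integrity genes averaged 69.6 and 23.5 bp (percentile 5.34; 1.88 with windows of 300 bp), with HSP150 at 461 and 0 bp, SLT2 at 500 and 174 bp and SWI4 at 0 and 320 bp. Meiosis and sporulation genes averaged 229 and 165 bp (percentile 2.96; 2.41 with lists of the same number), with MER1 at 405 and 38 bp, HOP1 at 228 and 4 bp and SPO13 at 290 and 87 bp. The subtelomeric PAU and COS families averaged 160 and 118 bp (percentile 4.80), with PAU7 at 258 and 0 bp, COS9 at 240 and 0 bp and PAU20 at 500 and 343 bp. Auxotrophic marker genes averaged 212 and 181 bp (percentile 6.24), with ADE2 at 500 and 340 bp and MET17 at 484 and 427 bp. LEU2 held 500 bp in both, and since BY4741 is known to lack LEU2 and MET17, the origin of their signal and so of this mean is unknown. Over all 23 lists, 17 had more WT-only than G170D-only promoters, 3 had more G170D-only promoters and 3 had as many of each. Among all 6002 genes WT-only promoters were also more frequent, at 423 against 299. Some lists differed by a single gene, as the RSC list did with 1 and 0.

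**Figure D2:**
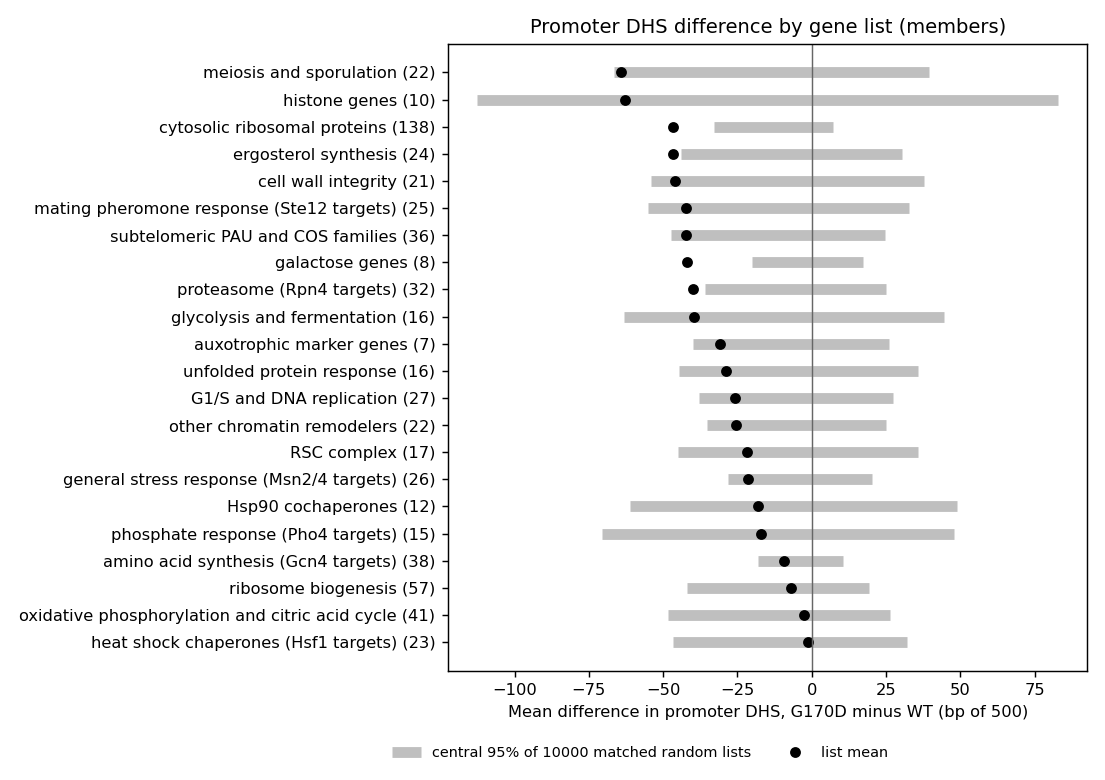
Mean difference in promoter DHS length (bp of the 500-bp window, G170D minus WT, x axis) for 22 gene lists with the number of members in brackets; points are list means and grey bars the central 95% of 10000 matched random lists. The Hsp90 list of 2 genes is not drawn, and the points of the ribosomal protein, proteasome, galactose and ergosterol lists lie left of their bars.

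Footprints were fewer in G170D on each of the 16 chromosomes. The ratio of footprint number, G170D to WT, was 0.746 (0.736 to 0.757) overall and 0.832 (0.820 to 0.845) in the 1544.5 kb that DHS of both strains covered, where WT held 23.2 and G170D 19.3 footprints per kb. By chromosome the ratio ran from 0.647 on chromosome IX and 0.656 on VI to 0.795 on XVI, and the highest was 1.23 times the lowest. Within the shared length the spread over chromosomes was smaller, at 1.06 times. Of WT footprints in the shared length, 61.2% (60.7 to 61.7) overlapped a G170D footprint, against 45.4% after random offsets, and 72.7% (72.2 to 73.2) of G170D footprints overlapped a WT footprint, against 53.3%. Among the strongest decile by score 94.3% of WT and 95.6% of G170D footprints overlapped one of the other strain, and among the weakest decile 38.0% and 52.3%. The shares of the weakest decile lay below the averages after random offsets. They therefore show no recurrence of the weakest footprints beyond that of unrelated ones. Random offsets were not drawn for single deciles. Which proteins the footprints belonged to was not analysed here.

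**Figure D3:**
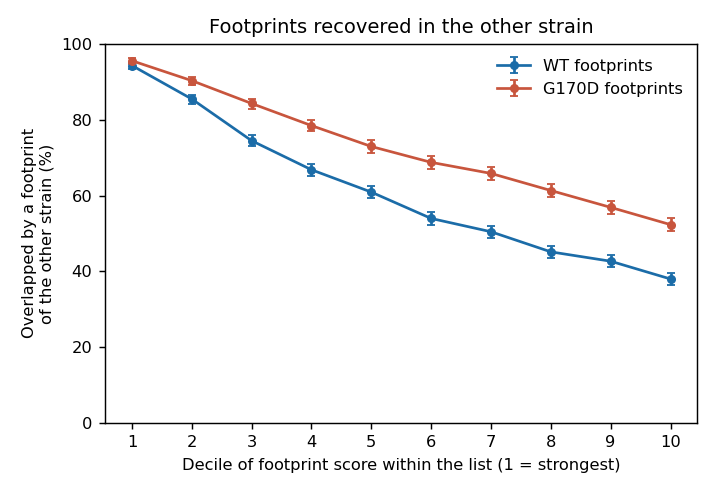
Share of footprints in the length covered by both strains that overlapped a footprint of the other strain (%, y axis), by decile of the footprint score within each list (x axis, 1 strongest); blue points are WT footprints, red points G170D footprints, and bars exact 95% intervals. The share runs from 94.3% to 38.0% for WT and from 95.6% to 52.3% for G170D. Averages after random offsets, over all deciles together and not drawn, were 45.4% for WT and 53.3% for G170D.

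Of coding starts, coding ends and tRNA gene starts, DHS coverage was highest at tRNA genes and next highest after coding ends. Of 275 tRNA genes, 216 (78.5%, 73.2 to 83.2) overlapped a DHS in WT and 200 (72.7%, 67.1 to 77.9) in G170D, with 192 in both, 24 in WT only and 8 in G170D only. Coverage peaked 200 to 300 bp after the tRNA gene start, at 88.7% in WT and 76.5% in G170D. Around coding ends it peaked 200 to 300 bp after the end, at 30.7% and 26.8%, and around coding starts the highest values were 19.9% and 18.3%. DHS midpoints lay within 500 bp upstream of a coding start for 28.5% of WT and 31.7% of G170D regions, and these windows made up 21.3% of the chromosomes. Within 500 bp downstream of a coding end, a window chosen after the data were seen, the shares were 42.7% and 42.4%, and these windows made up 21.9%. Intergenic spaces without tRNA genes were covered over 41.8% of their length in WT and 38.4% in G170D where 2 genes converged, 26.8% and 23.0% where genes were in tandem, and 18.8% and 16.4% where 2 genes diverged.

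**Figure D4:**
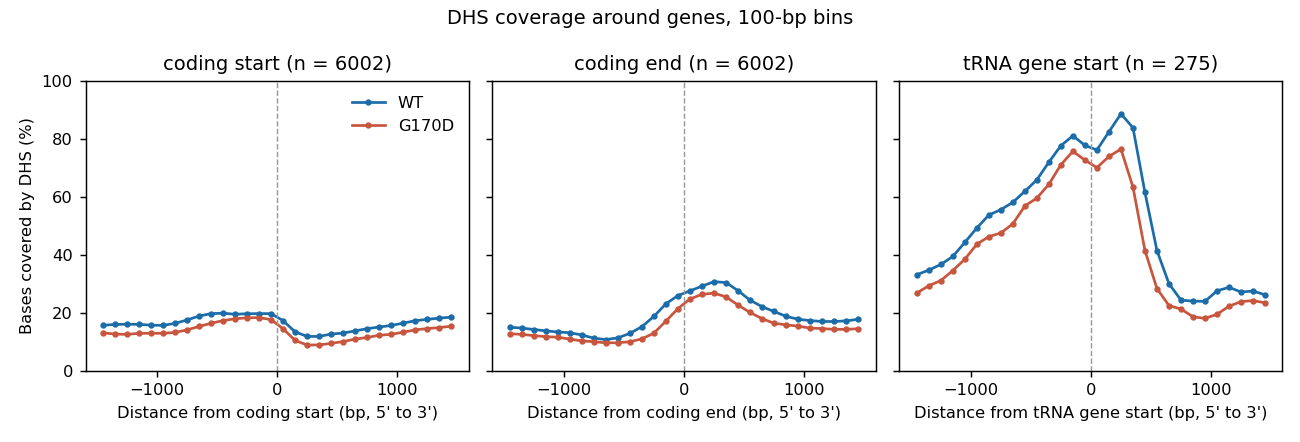
Share of bases covered by DHS (%, y axis) in 100-bp bins against distance (bp, x axis, 5' to 3') from 6002 coding starts, 6002 coding ends and 275 tRNA gene starts, with WT in blue and G170D in red. Coverage reaches 88.7% in WT and 76.5% in G170D after tRNA gene starts, 30.7% and 26.8% after coding ends, and 19.9% and 18.3% before coding starts.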

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

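Common score thresholds for footprints, promoters with no DHS of the other strain within 150 bp, and the windows after coding ends and around tRNA genes were alternatives chosen after the data were seen. The share of DHS with no counterpart was, for WT and G170D, 50.2% and 45.3% with overlap of at least 50% of each DHS, 5.45% and 3.62% for DHS of at least the median width, and 24.3% and 20.1% with lists of the same number, so WT kept the higher share in each. Settings with 1 score threshold for both strains compare scores across lists, whose common scale is not known. The footprint ratio was 0.766 with a common score threshold. Within the shared length it was 0.852 with that threshold, 0.791 for footprints stronger than the WT median score, and 0.746 when DHS of either strain counted, which equals the overall ratio by construction because every footprint lies in a DHS of its own list. The limit of 6 to 30 bp removed no footprint. The share of DHS midpoints near coding starts was 19.2% and 21.3% within 300 bp upstream and 46.3% and 48.3% within 1000 bp, which follows from the window size. It was 42.7% and 42.4% after coding ends and 7.07% and 7.72% around tRNA genes. With windows of 300 bp, 2 gene lists in place of 4 lay outside the central range, and 3 did in each of the other settings. Genes with a WT-only promoter DHS numbered 343 to 433 and with a G170D-only promoter DHS 250 to 326 over the alternatives. The 2 counts were closest with lists of the same number, at 372 and 326. In all, 24 recalculations of main values stayed within the interval of the main value or, where it had none, within 1.5 times. Among these were the promoter counts, the number of lists outside in settings other than windows of 300 bp, and the 6 to 30 bp limit. The other 19 recalculations moved further. For gene lists the number outside was compared, and which lists lay outside differed between settings. The mean difference of 21 of 23 lists kept its sign in each alternative, the exceptions being heat shock chaperones and oxidative phosphorylation. Apart from settings whose construction sets the value, the cause was not tested. The motif alternatives were not run. No paired analysis was possible because each strain had 1 library. Read depth was unknown, which limits every difference in list length.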

Other observations

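Of the tests below, that of a long copy gain was fixed before its result was seen, and the others, the choice of strong regions and the genes named here were chosen after related values had been seen.

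Small nucleolar RNA genes, whose products guide modification of ribosomal RNA, were also examined. Of 76 such genes, 44 overlapped a DHS in WT and 30 in G170D, with 27 in both, 17 in WT only and 3 in G170D only (SNR80, SNR191 and SNR36). Of those with a WT DHS, 38.6% (24.4 to 54.5) had none in G170D, and the value was 11.1% (7.25 to 16.1) for tRNA genes and 22.3% (20.4 to 24.2) for promoters. RNA genes were scored over the gene and promoters over 500 bp, and the differences between these shares were not tested. Neighbouring genes that share a DHS were counted separately, so these intervals can be too narrow. In the other direction the shares were 10% (2.11 to 26.5), 4% (1.74 to 7.73) and 16.8% (15.1 to 18.7). The WT-only genes included SNR65 and SNR189 on chromosome III, on either side of the ribosomal protein gene RPS14A (III:177500-178220), and SNR128 and SNR190 on chromosome X, next to RPA34 (X:140437-141138).

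LEU2 (III:91324-92418) was covered by DHS over its whole coding length of 1095 bp in both strains, with 44 footprints in WT and 31 in G170D, although BY4741 is known to lack LEU2, MET17 and URA3. URA3, HIS3 and LYS2 held no DHS in promoter or coding region in either strain, and MET17 held 90 bp in WT and 67 bp in G170D within its coding region and 484 and 427 bp in its promoter window. TRP1 (IV:461842-462516) held 646 bp of DHS and 14 footprints in its coding region in WT against 88 bp and 1 footprint in G170D. Its neighbour GAL3 had a promoter DHS in WT only. Whether a plasmid or marker in the strains gave the LEU2, MET17, TRP1 and GAL3 values was not tested, so they cannot be read as chromosomal chromatin alone, nor can the part of the galactose list that rests on GAL3.

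Narrow, weak regions made up most DHS found in WT alone. A lower depth or a higher effective threshold in the G170D library is a candidate explanation: it needs strong WT regions to be kept, and 0.127% of the top quartile of WT DHS by score had no G170D counterpart against 65.5% of the lowest quartile. The same gradient was seen in the other direction, from 39.9% of the lowest quartile of G170D DHS to 2.37% of the top quartile. In both lists, weak regions thus made up most of the regions without a counterpart. Overlap needed 1 bp, however, and wide regions meet a counterpart more easily than narrow ones. The median width in WT was 720 bp for shared regions and 194 bp for WT-only regions. The gradient by score was not separated from width, so it does not decide for or against depth or threshold. An effect of the Hsp90 allele on weak regions stays open and untested, because strain and library cannot be separated with 1 library each.

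Strong regions found in G170D alone, in the top decile of their list by score, numbered 8, at PDR15, RSM7, SRX1, SPO24, ACH1, SCS3, ATP2 and the coding end of ART5 (VII:624852-625822, apart from the weaker region at the ART5 and ROM1 promoters), 869 to 1180 bp wide, against 0 in WT (upper limit 1.16%), and 6 of the 8 held a coding start, as did 37.1% of other such DHS. Of the other top-decile G170D DHS, 51.1% lay within 500 bp of a tRNA gene, against 0 of the 8 regions. The shares with a coding start thus do not compare like regions, and the difference was not tested. A lower depth of the WT library as a whole cannot be decided from the lists. WT held more footprints in the length covered by both strains (G170D to WT ratio 0.832, 0.820 to 0.845). Footprint number also varies with threshold and with the footprints present, so this ratio does not give depth. A higher DHS threshold in WT stays open, since the lowest scores, 3.54 in WT and 3.48 in G170D, are not known to share a scale. A copy gain of a long segment also cannot be told apart: the G170D to WT ratio of DHS length from 1 to 10 kb on either side was 0.851, from 0.649 to 1.09 over the 8 regions, under the bound set in advance, but that bound was wrong because the lists give called lengths, which need not follow copy number. Extra DNA about as long as the regions cannot be told apart from open chromatin either, since the regions held 27.7 footprints per kb against 22.0 in other top-quartile G170D DHS and the lists carry no copy number, and a response of the G170D strain may equally apply and was not tested.

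More of the sequence after coding ends than before coding starts was DHS in both strains. Shifted coordinates are argued against, because profiles of Watson and mirrored Crick genes aligned best at a displacement of 15 bp. Nearby tRNA genes are argued against as the whole cause, because for the 5337 genes with no tRNA gene within 2 kb the WT ratio of coverage after ends to before starts was 1.57. Starts of the next gene are argued against as well, because convergent spaces, which hold no coding start, had 2.22 times the coverage of divergent spaces in WT and 2.34 times in G170D. Base composition and the fragment size selection stay open and were not tested, and the design names no biological group for this pattern, so no biological explanation was tested.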
